A study of Arabidopsis thaliana with 8 samples.

How the data were processed

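Messenger RNA was sequenced in 8 libraries of Arabidopsis seedlings, 2 each of 4 genotypes. Per the submitters' processing notes, HISAT2 2.0.4, featureCounts and edgeR were used with TAIR10. The deposited file holds normalised expression as a signal per gene, which the authors made as edgeR pseudo-counts at a common library size. This was established from the values: whole reads came out in 100% of values of each library when the pseudo-count step was inverted with a tolerance of 0.05, and rebuilding the values from those reads with edgeR gave back the deposited ones. Each mutant had been normalised with wild type in a run of its own, and the wild type columns come from the run with sdj1 sdj2 sdj3. The common size was 18968402 reads in that run, and 18397927 and 18413028 in those of suvh1 suvh3 and the quadruple mutant. These sizes differ from the first by -0.044 and -0.043 (log2). The normalisation factors of each run also enter the values, so the differences in size are not the offsets of these mutants' values. Library totals ran from 17667396 to 20662446 reads.

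The file lists 33977 features, of which 8793 are at 0 in all libraries. The 133 chloroplast-encoded and 152 mitochondrial-encoded features hold 0 reads in total over the 8 libraries, so these groups were not tested. Values were taken as log2(value + 1). The 22630 genes with a mean of at least 1 over all libraries entered one limma 3.58.1 fit (R 4.3.3) of the 4 genotypes, with moderated variances and a mean-variance trend. All 6 comparisons between genotypes were read from this fit, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. No label states that replicate numbers pair libraries of different genotypes, so no block entered. The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. A log-scale test had been planned for normalised values, and edgeR for a file of whole counts.

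On 5 simulated data sets with 200 changed genes each, for suvh1 suvh3 against wild type, the test recovered 59.8% of 2-fold and 90% of 4-fold changes. On average 16.2 of 166 calls were false, or 9.76%, which is above the nominal share. In a comparison with no changed genes it called 1 gene on average. The changed genes were drawn from genes with a higher mean than the filter required. The real comparison called 2 genes. With fewer calls the adjusted threshold asks for a smaller p, so the recovered shares do not apply to it directly.

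Genes were named by this rule. For each comparison with wild type, the mutated genes are named in every library, with the 10 largest changes in each direction among genes past the threshold whose mutant libraries both lie outside the range of the wild type libraries. Up to 4 members of each list past the threshold are named too. Between mutants the 5 largest in each direction are named, and across the mutants the 10 largest lower or higher in all 3. List members that passed only when adjusted over the list alone, the remaining called genes and those of the contrast of the mean of the mutants were chosen after their values were seen.

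The 22 gene lists, matched by locus, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. They were: auxin response; cell cycle; circadian clock; cold, drought and abscisic acid; DNA demethylation; DNA methylation; flavonoid and anthocyanin; flowering time and floral; genes known for promoter methylation; glucosinolate; heat shock. They also held iron deficiency, jasmonate, leaf senescence, mutated genes, other SUVH family, phosphate starvation, photosynthesis, root markers, salicylic acid defence, seed maturation and the unfolded protein response. With an estimated correlation 0 lists passed in any of the 3 comparisons with wild type, and the smallest adjusted p values were 0.342, 0.244 and 0.0676. By fry for movement in one direction 1 list, the mutated genes, passed in each. By fry for change in either direction, which compares no list with other genes, 5, 5 and 6 passed. The mutated, DNA demethylation and promoter methylation lists did so in every mutant, the cell cycle in suvh1 suvh3 and the triple mutant, DNA methylation in suvh1 suvh3 and the quadruple mutant, the clock in the triple and quadruple mutants, and seed maturation in the quadruple mutant. The mutated list holds the mutated genes themselves, so its passing was largely set by the design. ROS1 belongs to both the DNA demethylation and the promoter methylation list, so these results are not independent. Positions are from the TAIR10.1 annotation, since the file holds none. The annotation marks no transposable element genes, so the planned test of their distance to called genes was not run.

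Alternatives covered the pseudocount (0.1 and 5), the filter (none, or a mean of at least 5), quantile normalization, TMM factors from the values, fits of only the 2 genotypes compared, a replicate block, no trend, a robust trend, the edgeR 4.0.16 quasi-likelihood test on the recovered reads (20365 genes) and leaving out each library in turn. The edgeR exact test with each mutant and wild type in a run of its own, the contrast of the mean of the 3 mutants, the counts of clock genes without each library, the count of called genes near only the loci that each mutant's label lists, the overlaps with other scalings and without the 4 followed loci, and the simulated covariance at a pseudocount of 0.1 were chosen after seeing the data. Where a genotype is left with 1 library, that library is assumed to vary like the others. Overlaps between mutants were set beside 100 simulated data sets with no genotype effect and the same shared wild type libraries, and covariances without 1 wild type library beside as many that share the other. Floors cover counting error only. Figures were drawn with matplotlib 3.10.9.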

Results

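Messenger RNA of 12-day-old Arabidopsis seedlings was sequenced in 4 genotypes with 2 libraries each: wild type, the double mutant suvh1 suvh3, the triple mutant sdj1 sdj2 sdj3 and the quadruple mutant suvh1 suvh3 sdj1 sdj3. SUVH1 and SUVH3 encode proteins that bind methylated DNA, and the SDJ genes encode DNAJ-domain proteins. The stated purpose of the series is to learn what a complex that binds methylated DNA does for plant development and for the activity of genes with methylated promoters. Seedlings grew at 22 °C with 16 h light and 8 h dark. Reads recovered from the deposited values came to 18574264 and 18224542 in the wild type libraries, 17667396 and 19157321 in suvh1 suvh3, 18508576 and 20662446 in sdj1 sdj2 sdj3, and 18281717 and 18574435 in the quadruple mutant. Levels are normalised read counts scaled by the authors to a common library size within each run of a mutant with wild type. The sizes of the suvh1 suvh3 and quadruple runs differ from that of the wild type columns by -0.044 and -0.043 (log2). Normalisation factors of each run enter as well, and the median log2 fold changes of all genes against wild type were -0.046 and 0. No label states that the 2 libraries of a genotype came from separate plants, so the p-values measure the spread between these samples.

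The mutated genes were read in every library first, each beside its wild type level. SUVH1 (AT5G04940, chromosome 5, 1454131 to 1457141, TAIR10.1) stood at 432 ± 1.3 (SD, n = 2) in wild type. It stood at 82.2 and 119.8 in the suvh1 suvh3 libraries, which is 19% and 27.8% of the wild type mean, and at 158.5 and 150.6 in the quadruple mutant. In sdj1 sdj2 sdj3, where SUVH1 is intact, it stood at 476.4 and 429.3. SUVH3 (AT1G73100, chromosome 1, 27491184 to 27494182) stood at 434 and 441.2 in wild type and at 68.5 and 63 in the quadruple mutant. In the library labelled suvh1 suvh3 replicate 1 it stood at 428.2, or 97.9% of the wild type mean, whereas replicate 2 had 116.8, or 26.7%. The annotation places parts of AT1G09367 and AT1G73110 over SUVH3. The labels give no loci for the SDJ genes. 2 loci entered as SDJ genes before the data were examined, AT5G64360 as SDJ1 and AT1G62970 as SDJ2, were followed by locus. The label of the quadruple mutant lists sdj1 and sdj3 but not sdj2, so which of its mutations, if any, AT1G62970 carries is not known from the labels. AT5G64360, annotated as EIP9, stood at 406 and 515.6 in wild type, 332.3 and 382.8 in suvh1 suvh3, 116.8 and 102.3 in sdj1 sdj2 sdj3, and 52.4 and 68.9 in the quadruple mutant. AT1G62970 stood at 713.6 and 698.5 in wild type, 529.9 and 597.1 in suvh1 suvh3, 211.5 and 212.9 in sdj1 sdj2 sdj3, and 262.9 and 178.1 in the quadruple mutant.

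**Figure D1:**
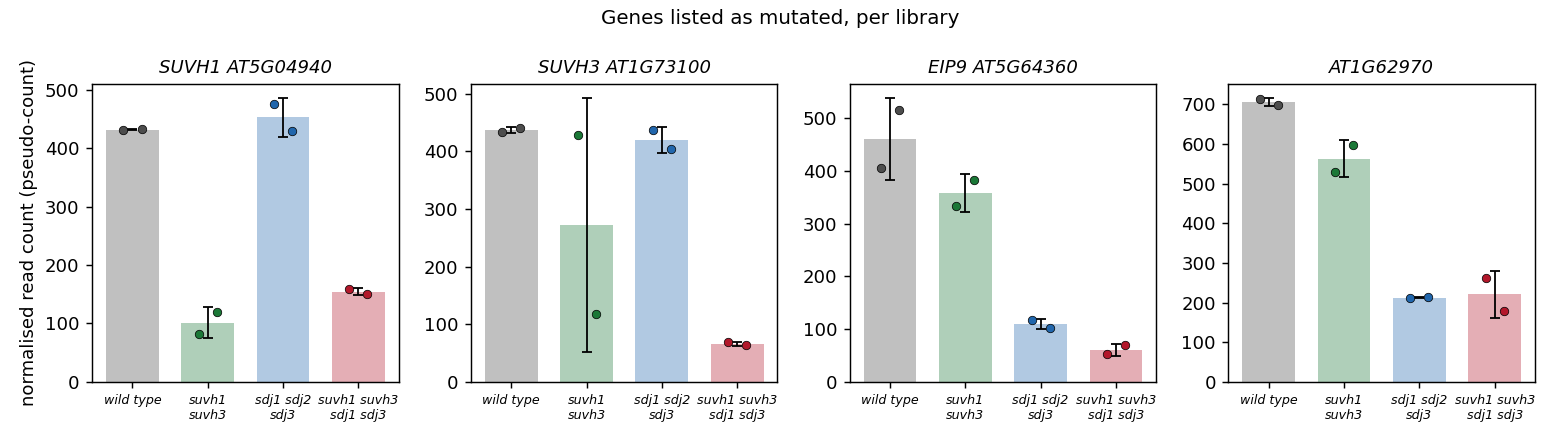
Normalised read count (pseudo-count, linear axis from 0) of SUVH1, SUVH3, EIP9 and AT1G62970 in each of the 4 genotypes; points are libraries, bars are means and error bars are SD (n = 2). SUVH3 is at 428.2 in the library labelled suvh1 suvh3 replicate 1 and at 116.8 in replicate 2.

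The libraries labelled suvh1 suvh3 were compared with wild type, a comparison meant to show which genes change without these DNA-binding proteins, although SUVH3 stood at its wild type level in replicate 1. CYCB1;5 (AT1G34460, chromosome 1, 12595110 to 12602379), annotated as a B-type cyclin, fell from 346 ± 8.3 to 33.7 ± 5.9 (SD, n = 2), 10.1-fold. Its log2 fold change was -3.33 ± 0.22 (SE, adjusted p = 0.00131 by limma), and both mutant libraries lay below both wild type libraries. The annotation places the noncoding RNA AT1G06757 over part of this gene. SUVH1 fell 4.32-fold, with a log2 fold change of -2.11 ± 0.19 (adjusted p = 0.00861). SUVH3 did not pass, at -0.96 ± 0.45 (adjusted p = 1 by limma), and stood at -1.9 (adjusted p = 0.0251) without the library labelled suvh1 suvh3 replicate 1 and at -0.03 (adjusted p = 0.993) without replicate 2. Of 22630 genes tested with limma, 2 were lower and 0 were higher, beside 576 and 234 at an unadjusted p under 0.05. The edgeR quasi-likelihood test called 2 genes in all, both shared with limma, and the edgeR exact test called 28, of which 6 were higher. Without the library labelled suvh1 suvh3 replicate 1, 5 genes were lower, and without either wild type library 0 were lower. The median log2 fold change of all genes was -0.046 with the authors' scaling. The common library size of this mutant's run was smaller, a difference of -0.044 (log2), and the normalisation factors of the run enter as well. The median was -0.103 with TMM factors computed from the values and -0.001 in the edgeR quasi-likelihood test on the recovered reads. The share of genes at an unadjusted p under 0.05 that were lower moved with the median, from 71.1% to 88.1%. It was 51.1% after quantile normalization and 51.1% in the quasi-likelihood test.

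Among the gene groups, ROS1 (AT2G36490), which encodes a DNA glycosylase that removes methylated cytosine, fell from 2421 ± 144 to 1276 ± 153 (SD, n = 2) in suvh1 suvh3. Its log2 fold change was -0.93 ± 0.12 (SE), with an adjusted p of 0.000172 by limma when adjusted over the list alone and of 0.0803 over all genes. In the DNA demethylation list, 2 of 8 members fell adjusted over the list alone, the other being IDM3 at -0.99 ± 0.31, and 0 passed over all genes. ESP, which directs glucosinolate breakdown, was the 1 glucosinolate gene of 20 to pass adjusted over the list alone, at -1.55 ± 0.36. IRT1, the main root iron transporter, was 1 of 12 iron deficiency genes to pass in that way, at 0.63 ± 0.13. It was also the 1 of 18 root markers to pass. Of 22 lists, 4 passed camera with its preset correlation, and 7 did without either wild type library. Cold, drought and abscisic acid genes were lower (median log2 fold change -0.7, adjusted p = 1.39e-05, and adjusted p = 0.767 with an estimated correlation). Photosynthesis genes were lower (median -0.3, adjusted p = 0.000127, and adjusted p = 0.808 with an estimated correlation). Their median log2 deviation from the mean of the 8 libraries was 0.29 in replicate 1 and -0.26 in replicate 2 of this mutant. In wild type it was 0.38 and 0.31, so replicate 1 of the mutant lay near wild type. With limma, 0 of 22 passed adjusted over the list alone, beside 2 at an unadjusted p under 0.05, and 0 of 20 cold, drought and abscisic acid genes, beside 8. Iron deficiency genes were higher (median 0.31, adjusted p = 0.000839, and adjusted p = 0.767 with an estimated correlation). By library their median log2 deviation was 0.42 and 0.1, with replicate 2 inside the range of the wild type libraries at -0.28 and 0.23. For the cold, drought and abscisic acid list it was 0.03 and -0.48, against 0.25 in each wild type library. The list of 4 mutated genes, which also holds the AT5G64360 and AT1G62970 loci, was lower (adjusted p = 0.000498, and adjusted p = 0.342 with an estimated correlation), and 1 member, SUVH1, passed.

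The libraries labelled sdj1 sdj2 sdj3 were compared with wild type to ask the same of the DNAJ-domain partners. GH9B14 (AT4G09740, chromosome 4, 6142706 to 6145003), a glycosyl hydrolase gene, had 0 reads in wild type and 287 and 375 reads in sdj1 sdj2 sdj3. This is at least 100-fold higher when wild type is set at a floor of 3 reads per library (adjusted p = 0.0094 by limma). JMJD5 (AT3G20810, chromosome 3, 7275645 to 7278420), a histone demethylase gene linked to the circadian clock, rose from 463 ± 46.5 to 1159 ± 99.6 (SD, n = 2), 2.5-fold (adjusted p = 0.0264). The noncoding RNA AT3G05945 rose from 17.8 ± 11.6 to 267.9 ± 8.6 (adjusted p = 0.0198). CYCB1;5 fell 6.37-fold to 53.5 ± 2.7 (log2 fold change -2.67 ± 0.22, adjusted p = 0.00425). ROS1 fell 2.75-fold to 880.5 ± 80.8 (log2 fold change -1.46 ± 0.12, adjusted p = 0.00425). EIP9 fell 4.16-fold (adjusted p = 0.0094) and AT1G62970 fell 3.32-fold (adjusted p = 0.0103). The protein-coding gene AT5G11330 fell 2.38-fold, from 822 ± 2 to 345.5 ± 34 (adjusted p = 0.00425). AT2G18980, AT5G13980 and AT3G06355 also fell, by 1.07, 0.76 and 1.34 on the log2 scale. AT3G06355 is a noncoding RNA locus that overlaps the ribosomal RNA locus AT3G41979, and AT5G13980 overlaps AT5G13990. In limma 3 genes were higher and 8 lower, beside 578 and 641 at an unadjusted p under 0.05. The edgeR quasi-likelihood test called 13, sharing 10 with limma, and the exact test called 148. Without either wild type library limma called 0 genes, without sdj1 sdj2 sdj3 replicate 1 it called 3 lower and 0 higher, and without replicate 2 it called 4 lower and 0 higher. Leaving out replicate 1 or 2 of suvh1 suvh3 gave 6 or 7 higher and 11 or 13 lower, and leaving out replicate 1 or 2 of the quadruple mutant gave 2 or 1 higher.

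Clock genes moved in both directions in sdj1 sdj2 sdj3. Adjusted over the list alone, 5 of 18 fell and 5 rose by limma, while 0 passed over all genes, beside 13 at an unadjusted p under 0.05. The morning genes LHY and CCA1 fell by 0.67 and 1.0 on the log2 scale, with LNK2 (-1.11 ± 0.2), RVE8 and PRR7. The evening genes TOC1 (0.54 ± 0.13), BOA (0.86 ± 0.2), ELF4 and ELF3, and GRP7, rose. Camera, which asks for movement in one direction, gave an adjusted p of 0.965, and fry for change in either direction gave an adjusted p of 0.0373. The count was 2 without wild type replicate 2, 1 without sdj1 sdj2 sdj3 replicate 1, and 6 without either replicate of the quadruple mutant. Of 22 photosynthesis genes, 8 fell by limma adjusted over the list alone, 0 passed over all genes and 12 at an unadjusted p under 0.05. Among the 8 were LHCB1.1 (-1.62 ± 0.31), LHCB3 (-1.07 ± 0.28) and LHCA1 (-0.9 ± 0.24). The list had a median log2 fold change of -0.55 and an adjusted p of 4.38e-08 by camera, with adjusted p = 0.866 with an estimated correlation. LHCB1 and LHCB2 members are close paralogs, among which reads are hard to assign. NRPE1, the largest subunit of RNA polymerase V, was the 1 of 26 DNA methylation genes to pass adjusted over the list alone (-0.59 ± 0.12). AT3G01345, 1 of 7 measured genes entered as known for promoter methylation, rose by that measure (2.81 ± 0.63), and ROS1 of the same list fell. The defence genes PR2 (1.1 ± 0.24) and PR5 (0.55 ± 0.14) were 2 of 20 salicylic acid genes to pass, and IAA19 (0.95 ± 0.23) was 1 of 14 auxin response genes. Camera passed 6 of 22 lists, and 1 without sdj1 sdj2 sdj3 replicate 2. Beside photosynthesis these were the mutated genes (lower, adjusted p = 0.00384, and adjusted p = 0.244 with an estimated correlation) and the cell cycle (lower, adjusted p = 0.00486, and adjusted p = 0.244 with an estimated correlation). The others were DNA methylation (lower, adjusted p = 0.0228), cold, drought and abscisic acid (lower, adjusted p = 0.0375) and the unfolded protein response (higher, adjusted p = 0.0375), each with adjusted p = 0.866 with an estimated correlation. The median log2 deviation of the DNA methylation list was -0.07 and 0.01 in the triple mutant, the latter inside the range of the wild type libraries at -0.01 and 0.12. sdj1 sdj2 sdj3 replicate 1 lay apart from the other libraries on the second principal component (-58.9), which held 15.6% of the variance.

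The quadruple mutant was compared with wild type to show the state with mutations in both gene families. EIP9 fell 7.5-fold to 60.7 ± 11.7 (SD, n = 2; log2 fold change -2.91 ± 0.2, adjusted p = 0.00185 by limma). CYCB1;5 fell 4.91-fold to 69.6 ± 1 (log2 fold change -2.3 ± 0.22, adjusted p = 0.0125). PORA, a protochlorophyllide oxidoreductase of chlorophyll synthesis, fell 4.21-fold from 487.5 ± 101 to 116.2 ± 33.4 (adjusted p = 0.0215). RLP19, a receptor-like protein gene, fell 2.46-fold from 1412 ± 45.2 to 574.4 ± 61.9 (adjusted p = 0.00821). SGS3, which acts in RNA silencing, fell 2.02-fold from 804.5 ± 13.5 to 398.5 ± 51.8 (adjusted p = 0.0406). ROS1 fell 1.87-fold to 1292 ± 91.8 (adjusted p = 0.0406). AT1G62970 fell 3.25-fold and SUVH1 2.78-fold, and AT4G12917 and AT3G47250 fell by 2.32 and 0.91 on the log2 scale. AT5G13980 and the formate dehydrogenase gene FDH fell by 0.85 and 0.81. AT3G01345 rose from 8.4 ± 4.4 to 497.7 ± 260 (log2 fold change 5.71 ± 0.63, adjusted p = 0.0215). JMJD5 rose 2.39-fold to 1103 ± 11.2 (adjusted p = 0.0344), and AT5G59670 rose 2.27-fold (adjusted p = 0.0406). SUVH3 stood at -2.72 ± 0.45 and did not pass (adjusted p = 0.146); it passed without the library labelled suvh1 suvh3 replicate 1 (adjusted p = 0.000567) or without replicate 2 (adjusted p = 0.000322). In limma 3 genes were higher and 12 lower, beside 889 and 1209 at an unadjusted p under 0.05, which became 1056 and 1016 after quantile normalization. The edgeR quasi-likelihood test called 13, all shared with limma, and the exact test called 249. Without wild type replicate 1 limma called 1 lower gene and 0 higher, without wild type replicate 2 it called 0, and without replicate 1 or 2 of the quadruple mutant it called 3 or 1 lower and 0 higher. Leaving out a library of sdj1 sdj2 sdj3 left 4 lower genes in either case, and 0 or 1 higher.

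The clock pattern of the triple mutant was present in the quadruple mutant as well, where 5 of 18 genes rose and 6 fell by limma adjusted over the list alone, and 0 passed over all genes, beside 13 at an unadjusted p under 0.05. LHY (-0.85 ± 0.16), CCA1 (-1.09 ± 0.23), LNK2 (-1.16 ± 0.2), PRR7, RVE8 and RVE4 fell. TOC1 (0.44 ± 0.13), BOA (0.81 ± 0.2), ELF4, GRP7 and GRP8 rose. The count was 6 without wild type replicate 2 and 7 without replicate 2 of the quadruple mutant, and the adjusted p was 0.827 by camera and 0.0304 by fry for change in either direction. In suvh1 suvh3, 0 of 18 clock genes passed limma or either edgeR test adjusted over the list alone, beside 2 at an unadjusted p under 0.05 in limma, and fry for either direction gave an adjusted p of 0.998. There 3 passed without wild type replicate 2, and 1 without the library labelled suvh1 suvh3 replicate 1. Photosynthesis genes had a median log2 fold change of -0.59, and 11 of 22 fell adjusted over the list alone, among them LHCB1.1 (-1.64 ± 0.31), LHCA4 (-0.94 ± 0.24) and LHCB5 (-0.64 ± 0.22). Their camera adjusted p was 7.68e-10, with adjusted p = 0.639 with an estimated correlation. NRPE1 (-0.54 ± 0.12) and NRPD2 (-0.44 ± 0.1), subunits of the RNA polymerases of RNA-directed DNA methylation, were the 2 of 26 DNA methylation genes to pass adjusted over the list alone. ESP (-1.99 ± 0.36), HSP90.1 (0.8 ± 0.14), PR5 (0.88 ± 0.14) and PR2 (0.89 ± 0.24) passed in their lists by the same measure. Camera passed 6 of 22 lists, of which the mutated genes were lower (adjusted p = 3.36e-09, and adjusted p = 0.0676 with an estimated correlation). Phosphate starvation genes were higher (adjusted p = 0.0201, and adjusted p = 0.759 with an estimated correlation), as were those of the unfolded protein response (adjusted p = 0.0201, and adjusted p = 0.639 with an estimated correlation). The median log2 deviation of the phosphate starvation list was 0.34 and 0.29 in the quadruple mutant, near wild type replicate 1 at 0.29 and above wild type replicate 2 at -0.51. DNA demethylation genes were lower (adjusted p = 0.0216, and adjusted p = 0.639 with an estimated correlation), as were cold, drought and abscisic acid genes (adjusted p = 0.0216, and adjusted p = 0.759 with an estimated correlation). The median log2 deviation of the DNA demethylation list was -0.14 and -0.02 in the quadruple mutant, the latter inside the range of the wild type libraries at -0.03 and 0.2, and 1 of 8 members, ROS1, passed adjusted over the list alone. Replicate 1 of the quadruple mutant lay apart on the first principal component (70.5), which held 22.3% of the variance. The median log2 deviation of the photosynthesis list from the mean of the 8 libraries was -0.44 in that library and -0.07 in replicate 2.

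**Figure D2:**
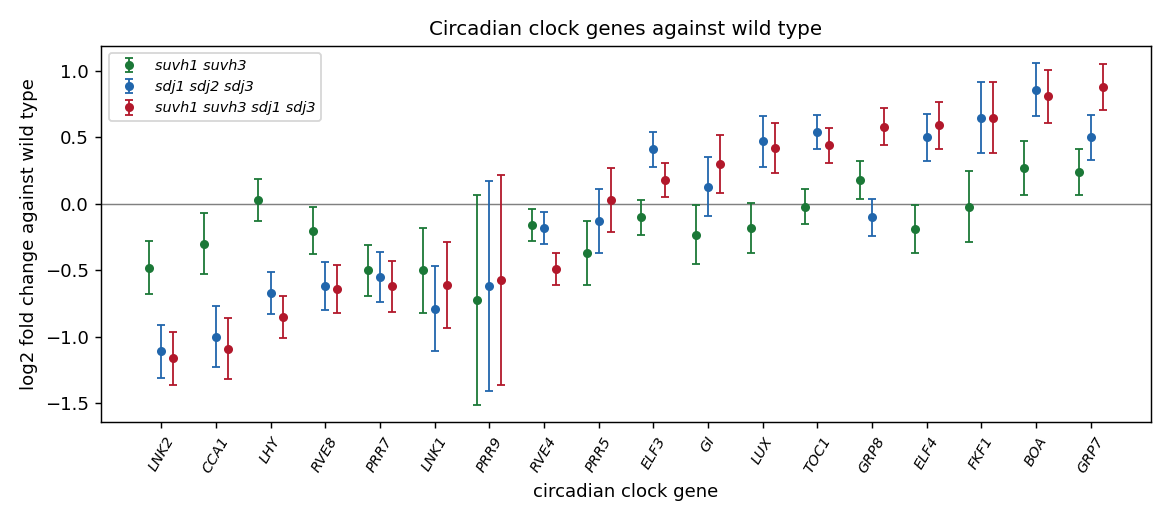
Log2 fold change against wild type (linear axis) of the 18 circadian clock genes in the 3 mutants; points are limma estimates and error bars are SE (n = 2 libraries per genotype). LNK2 is at -1.11 and -1.16 in the triple and quadruple mutants, and BOA at 0.86 and 0.81.

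Across the 3 mutants, CYCB1;5 was the 1 gene lower in all of them, and 0 genes were higher in all of them by limma or by the edgeR quasi-likelihood test, while the exact test gave 1. Since every mutant is compared with the same 2 wild type libraries, some overlap arises without any effect. In 100 simulated data sets with no genotype effect, the highest number lower in all 3 was 1, as many as observed, and the mean rounded to 0. Independent lists would share 3.75e-07. At an unadjusted p under 0.05, 104 genes were lower in all 3, against a simulated mean of 50.2 and a highest of 70. 57 were higher, against a simulated mean of 49.7 and a highest of 68. The 104 and 57 became 84 and 83 after quantile normalization, 147 and 43 with TMM factors, and 96 and 63 in the edgeR quasi-likelihood test, so their balance depends on the scaling. The triple and quadruple mutants shared 5 lower genes, 2 of them at the followed loci EIP9 and AT1G62970, and 1 higher gene. In the simulated data sets this pair shared 0.1 higher genes on average and at most 2. suvh1 suvh3 and the quadruple mutant shared 2 lower genes, CYCB1;5 and the mutated SUVH1, and suvh1 suvh3 and sdj1 sdj2 sdj3 shared 1. Without the 4 followed loci the lower genes shared came to 3, 1 and 1, against simulated means of 0.06, 0.08 and 0.06 and a highest of 1 for each pair. The covariance of fold changes between mutants across genes was 0.108, 0.111 and 0.12 for the 3 pairs, against 0.085, 0.086 and 0.085 in simulated unchanged groups. Genes are not independent replicates. Without wild type replicate 1 the covariances were 0.21, 0.223 and 0.232, against 0.171 for each pair in simulated unchanged groups that share 1 wild type library. Without wild type replicate 2 they were 0.182, 0.174 and 0.183, against 0.172, so the excess over no change was 0.01, 0.003 and 0.012. Without either wild type library 0 genes were lower in all 3. None was lower in all 3 without replicate 2 of the quadruple mutant, and 2 were without the library labelled suvh1 suvh3 replicate 1.

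A contrast of the mean of the 3 mutants against wild type, added after the data had been seen, called 14 genes lower and 2 higher in limma, beside 870 and 592 at an unadjusted p under 0.05. CYCB1;5 fell by 2.77 ± 0.18 (SE) on the log2 scale (adjusted p = 0.00113), and ROS1 by 1.1 ± 0.1 (adjusted p = 0.0085). PORA, SGS3 and RLP19 fell by 1.7, 1.01 and 0.93, and the cytochrome P450 gene CYP702A5 fell by 1.89. JMJD5 rose by 1.04 ± 0.13 (adjusted p = 0.0261). Its means were 684.5 in suvh1 suvh3 and 1159.3 and 1102.5 in the triple and quadruple mutants, where clock genes also moved. Whether harvest time accounts for the rise of JMJD5 was not tested. AT3G05945 passed at 2.77, although it stood at 24.4 ± 4 (SD, n = 2) in the quadruple mutant, near its wild type level. Without the library labelled suvh1 suvh3 replicate 1 this contrast called 30 lower genes and 8 higher, and without either wild type library 0. It called 6 lower genes and 0 higher without replicate 1 of sdj1 sdj2 sdj3, 1 higher without replicate 2, and 4 higher without replicate 2 of suvh1 suvh3. It called 6 or 8 lower genes and 0 higher without replicate 1 or 2 of the quadruple mutant.

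**Figure D3:**
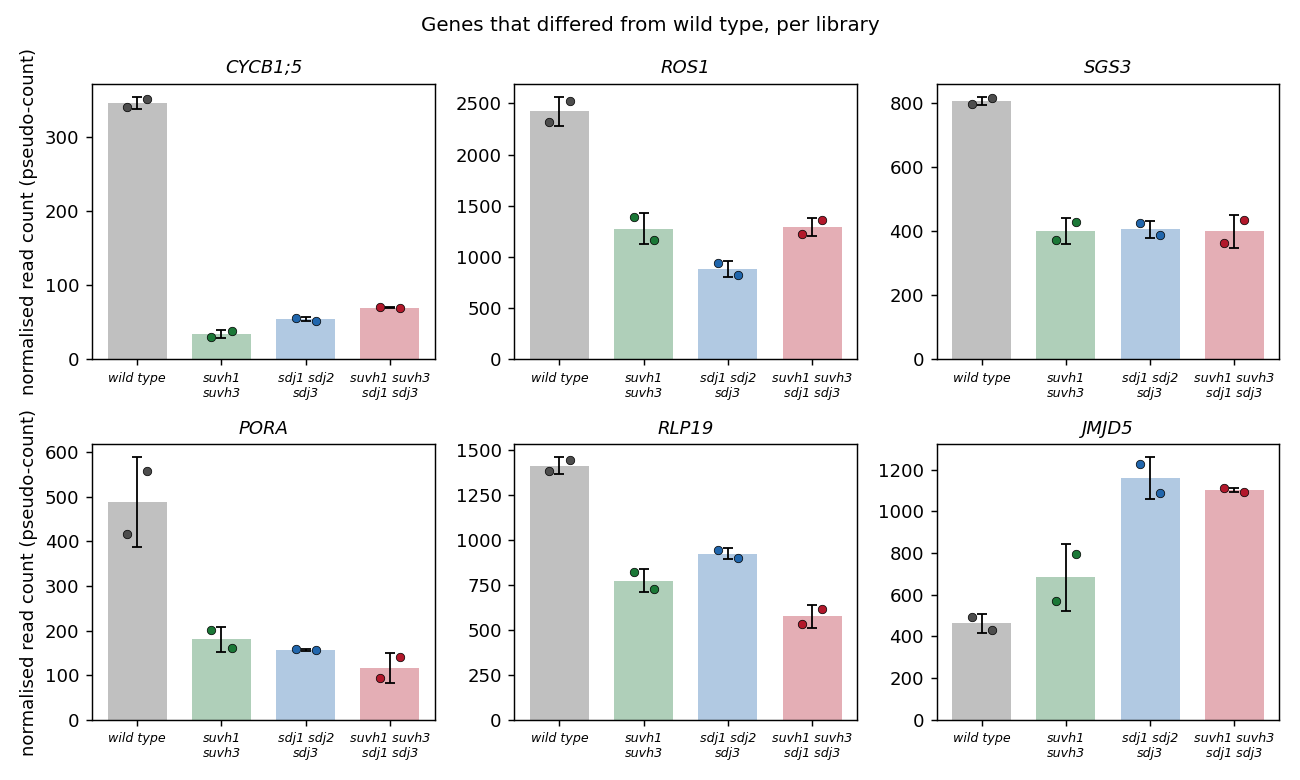
Normalised read count (pseudo-count, linear axes from 0) of CYCB1;5, ROS1, SGS3, PORA, RLP19 and JMJD5 in each of the 4 genotypes; points are libraries, bars are means and error bars are SD (n = 2). SGS3 has means of 804.5 in wild type and 399.1, 404.4 and 398.5 in the mutants.

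The mutants were also compared with each other. By the labels, the quadruple mutant differs from the triple in suvh1 and suvh3 and also in sdj2, so that comparison isolates neither gene family. Between sdj1 sdj2 sdj3 and suvh1 suvh3, limma called 1 gene higher, the mutated SUVH1, and 1 lower, AT5G11330, at 345.5 ± 34 against 842.5 ± 3.8 (SD, n = 2). Between the quadruple mutant and suvh1 suvh3 it called 1 lower gene, EIP9, the locus entered as SDJ1, and 0 higher. Beside these, 824 were higher and 364 lower at an unadjusted p under 0.05, and 0 were higher by the edgeR quasi-likelihood test. The median log2 fold change of all genes there was 0.04, above 0. Between the quadruple and the triple mutant, AT5G11330 was higher, at 994.8 ± 14.4 against 345.5 ± 34, and GH9B14 was lower, with 0 reads in the quadruple mutant. The reads of GH9B14 in the triple mutant were at least 108-fold higher than a floor of 3 reads per library there. In the simulated data sets, where no gene was changed between the quadruple and the triple mutant, this comparison called 1 gene on average. ROS1, CYCB1;5 and JMJD5 passed in no comparison between mutants. Without replicate 1 of the quadruple mutant limma called 0 genes in these 3 comparisons. Without either wild type library it called 0 between the triple mutant and suvh1 suvh3, and 0 lower between the quadruple and the triple mutant. The genes lower than in suvh1 suvh3 were 0 in both comparisons without the library labelled suvh1 suvh3 replicate 1, and 3 and 5 without replicate 2. Without replicate 1 or 2 of sdj1 sdj2 sdj3, 0 were higher than in suvh1 suvh3 and 0 were lower in the quadruple than in the triple mutant. The last of these counts was 5 or 4 without replicate 1 or 2 of suvh1 suvh3.

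Genes within 2 Mb of any of the 4 followed loci were counted, since mutants can carry linked differences from their parents; a further SDJ locus was not covered. They made up 15.4% of the tested genes, and 0 of 1, 0 of 9 and 1 of 12 called genes other than those at the 4 loci in suvh1 suvh3, the triple and the quadruple mutant (Fisher's exact test, two-sided, p = 1, 0.371 and 1). With only the loci entered for genes that each label lists, a choice made after seeing the data, they made up 8.3%, 7.06% and 12% of the tested genes, and 0 of 1, 0 of 9 and 1 of 13 called genes (Fisher's exact test, two-sided, p = 1 in each). For the quadruple mutant this left out AT1G62970, entered as SDJ2, which is among its 13 called genes. AT1G62970 stood there at 37.2% and 25.2% of its wild type mean, so taking it as unmutated is doubtful. With so few called genes, these tests could show only a large excess near the loci. With the 1 called gene of suvh1 suvh3 they could show none, so linked differences stay open.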

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

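The tests of the SUVH3 and seed maturation patterns were chosen after the result was seen. Those of the clock pattern were set before their own results, but for a pattern in which clock genes had been seen to move in both directions.

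5 differences between the mutants themselves passed limma. In the simulated data sets, the comparison of the quadruple with the triple mutant held no changed genes and gave 1 call on average. SUVH1 was higher in sdj1 sdj2 sdj3 than in suvh1 suvh3 by 2.18 ± 0.19 (SE) on the log2 scale (adjusted p = 0.00653), and SUVH1 is mutated in the latter. AT5G11330 was lower in sdj1 sdj2 sdj3 than in suvh1 suvh3, at -1.29 ± 0.11 (adjusted p = 0.00653), and higher in the quadruple mutant than in the triple, at 1.53 ± 0.11 (adjusted p = 0.00211). EIP9, the locus entered as SDJ1, was lower in the quadruple mutant than in suvh1 suvh3, at -2.55 ± 0.2 (adjusted p = 0.00611). The label of the quadruple mutant lists sdj1, and that of suvh1 suvh3 does not. GH9B14 was lower in the quadruple than in the triple mutant, where the fitted log2 fold change of -8.3 ± 0.82 (adjusted p = 0.0235) rests on 0 reads and depends on the pseudocount.

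SUVH3 stood at the wild type level in the library labelled suvh1 suvh3 replicate 1. SUVH1 stood there at 0.19 of its wild type mean, which argues against wild type RNA in the library, and 0 of the other 7 libraries had a SUVH gene out of place, which argues against a swap among the 8. SUVH3 lay 0.345 above the midpoint of wild type and replicate 2, as a share of wild type, more than heterozygous plants would give if expression followed the number of alleles. A library of another genotype under this label stays open, since SUVH3 at 0.979 of its wild type mean is the observation itself. No biological explanation was tested, and another suvh3 allele stays open.

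Clock genes moved in both directions in the triple and quadruple mutants. Compared with suvh1 suvh3 in place of wild type, 11 of 18 passed adjusted over the list alone in the mean of both mutants, which argues against chance values of the shared wild type libraries. The median log2 fold change of evening genes minus that of morning genes was 1.15 (0.49 and -0.66), so harvest at another time of day may account for the pattern. The fold changes against wild type are those that showed the pattern, so these medians restate it and are no separate evidence for that explanation. Against suvh1 suvh3 these medians were 0.51 and -0.32, with a smaller morning shift in which PRR7 stood at -0.09 and PRR9 at 0.13. A difference in clock phase between genotypes would give the same values and was not tested; the labels give no harvest time.

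Seed maturation genes were high in replicate 1 of the quadruple mutant, where the median log2 deviation of the list from the mean of the 8 libraries was 1.95, against -0.22 in replicate 2. The median of all genes in that library lay 0.023 (log2) above the others, which argues against its scaling. Of 12 measured members 7 were highest there, among them CRU3 at 104.1 and CRU1 at 63.3 normalised reads, while EM1 was at 0. Seed or embryo tissue in that library could account for these 7, but the remaining members stood at or below 15.6 normalised reads in every library, too low to decide. No biological explanation was tested, as the other library of this genotype does not share the pattern.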

How the results depend on the processing

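The edgeR exact test and the counts for the mean of the 3 mutants, for the clock genes and near the loci each label lists, and the simulated covariance at a pseudocount of 0.1, were chosen after the result was seen. Of 37 named results, 31 past the threshold, 37 kept their direction and side with a pseudocount of 5 and with TMM factors, 35 with quantile normalization or a mean of at least 5, 34 with the quasi-likelihood test, 27 without a filter, 11 with only the 2 genotypes compared and 7 without a trend; 8 or 9 did so without 1 wild type library. The cause was not tested, except that fewer samples enter the fits of 2 genotypes and those without a library. Counts are given below as higher and lower against wild type (suvh1 suvh3, triple, quadruple), then between mutants (triple or quadruple against suvh1 suvh3, quadruple against triple).

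With the exact test counts against wild type were 6 and 22, 50 and 98, 81 and 168, with 1 higher and 13 lower in all 3. With a replicate block they were 1 and 8, 6 and 14, 21 and 80, with 4 lower in all 3, and between mutants 3 and 3, 1 and 6, 3 and 6; correlations of replicate deviations between genotypes of -0.02 to 0.11 do not show that the numbers pair the libraries, although replicate 1 lay above replicate 2 on the first principal component in all 4 genotypes, so pairing stays open. Without a trend 1 gene stayed lower in suvh1 suvh3, and the other counts against wild type and between mutants were 0, as was that lower in all 3. With a robust trend 6 were lower in suvh1 suvh3 and 4 in all 3, and between mutants 2 and 3 (triple against suvh1 suvh3) and 2 and 2 (quadruple against triple). With only the 2 genotypes compared, 1, 4 and 4 were lower, 0 higher in the quadruple and 0 lower in all 3; between mutants 0 and 0, 0 lower, and 0 higher. Without a filter, 1 was higher in the triple and 1 in the quadruple mutant. With quantile normalization 1 was higher in suvh1 suvh3, and 2 in the triple against suvh1 suvh3. For triple against suvh1 suvh3, the quasi-likelihood test gave 3 and 3 and a pseudocount of 5 gave 3 and 2. For genes lower in quadruple against triple, these gave 3 and 2, and a pseudocount of 0.1 or a mean of at least 5 gave 0. A pseudocount of 0.1 gave covariances of 0.298, 0.294 and 0.318, against 0.246 for each pair in simulated unchanged groups at that pseudocount. With an estimated correlation 0 lists passed camera in all 3 comparisons.

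Leaving out 1 library at a time gave these ranges: suvh1 suvh3 0 to 0 higher and 0 to 5 lower; triple 0 to 7 and 0 to 13; quadruple 0 to 3 and 0 to 15; triple against suvh1 suvh3 0 to 2 and 0 to 3; quadruple against suvh1 suvh3 0 to 1 and 0 to 5; quadruple against triple 0 to 2 and 0 to 5; all 3 mutants 0 to 0 and 0 to 2. The mean of the mutants gave 0 to 8 and 0 to 30. Covariances, which 1 shared wild type library raises by itself, ranged from 0.103 to 0.21, 0.101 to 0.223 and 0.107 to 0.232, lists past camera from 4 to 7, 1 to 8 and 4 to 7, and called genes near mutated loci from 0 to 1 in each. SUVH1 in the triple mutant, 0.07 with all libraries and not past the threshold, ranged from -0.01 to 0.14 without 1 library, -0.01 being without sdj1 sdj2 sdj3 replicate 1. Without a trend 2 clock genes passed in the triple mutant. At these depths a gene with 0 reads is bounded by a floor of 3 reads per library.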

Other observations

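The test of genes near pseudogenes was set before its result was seen, and its use in place of transposable element genes was chosen after the annotation had been examined.

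Lists not described so far passed camera in no comparison with wild type. In suvh1 suvh3, the triple and the quadruple mutant, the median log2 fold changes were 0.1, -0.01 and 0.06 for auxin response, 0.05, 0.04 and 0.03 for jasmonate, and 0.09, -0.23 and 0.22 for flavonoid and anthocyanin genes. Flowering time and floral genes had -0.13, -0.03 and 0.03, glucosinolate genes 0, -0.03 and 0.01, and heat shock genes -0.19, 0.09 and 0.04. Leaf senescence genes had -0.06, -0.03 and -0.2, root markers 0.03, -0.11 and 0.04, and salicylic acid defence genes -0.08, 0.05 and 0.15. The other SUVH family genes had -0.08, 0.02 and -0.01 (6 measured), and genes known for promoter methylation 0.48, 0.19 and 0.79 (7 measured, ROS1 lower among them). Seed maturation genes had -0.4, -0.15 and 1.02, the last of these with an adjusted p of 0.0557 by camera. The signs of median and camera test differed for salicylic acid defence in suvh1 suvh3; for auxin response, flowering time, phosphate starvation and promoter methylation genes in the triple mutant; and for flowering time, glucosinolate and other SUVH family genes in the quadruple mutant.

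A hypothesis was that genes close to annotated pseudogenes, many of which are transposon remnants, fall more than other genes in the mean of the 3 mutants. The 934 genes with a pseudogene within 2 kb had a median log2 fold change of -0.031 against -0.015 elsewhere, and 98.3% of 10000 random lists matched on expression had a higher median. Genes near pseudogenes may thus lie slightly lower, though the shift is small and neighbouring genes are not independent. Of 11 genes called lower in that contrast and not mutated themselves, 2 lay within 2 kb of a pseudogene (Fisher's exact test, two-sided, p = 0.0732), against 1 of 11 within 1 kb (p = 0.235) and 2 of 11 within 5 kb (p = 0.236) by the same exact test.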
